A study of Drosophila melanogaster with 2 samples.

How the data were processed

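RNA immunoprecipitation (RIP), in which an antibody is used to pull a protein from a lysate together with the RNA it carries, was followed by RNA sequencing of ovaries from the wild-type Drosophila melanogaster strain Oregon-R. Per the labels, ovaries came from females at most 12 hours after eclosion, about 200 females went into each RIP, and 1 ovarian lysate was divided between an anti-Lsd1 reaction and a control reaction. The control is titled IgG-RIP, and the antibody its label names is against GFP. It is called the IgG-RIP library here. Per the labels' protocols, libraries were made with a TruSeq RNA version of the kit that does not mark strand, and the poly(A) selection step was skipped. There were 2 libraries, 1 per group, with no replicates and no input library among the samples analysed here, so no test between conditions was possible and no p-value is given.

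The values used were gene FPKM, fragment numbers scaled by transcript length and by the size of the library, as deposited by the authors, 1 table per library, each with the lower and upper bound of an interval on each FPKM and a status per gene, per the file headers. The submitters' processing notes name Bowtie2 2.0.6.0, SAMtools 0.1.18.0, Cufflinks and the dm6 genome build, without giving their roles. The version of Cufflinks and the gene annotation are not given in the sources used here. Each table had 17720 genes with FlyBase gene numbers. Loci are given on dm6, counted from 1. Biotypes came from a table of NCBI's Release 6 plus ISO1 MT assembly, which matched 17655 of the 17720 genes. Mitochondrially encoded genes, tRNA and miRNA precursors were listed at 0 in both libraries. The status HIDATA, which marks loci with too many fragments to be estimated, was given to 25 loci, with FPKM 0. Of these, 23 were ribosomal RNA loci and 2 were miRNA precursors. An FPKM of 0 can therefore be a failed estimate, and such genes are described only as listed at 0, with no fold.

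Read counts were not used here. The deposited bounds were taken to lie 2 standard deviations from the FPKM and to reflect counting error, and an approximate number of fragments per gene was derived as the square of 2 times the FPKM over the distance to the upper bound. Of 7225 such values between 0.5 and 30, 41.7% lay within 0.02 of a whole number, so they are approximate. For genes with several isoforms the bounds may also hold uncertainty of assignment. Between the libraries, 518 genes with whole fragments shared 1 ratio of fragments per FPKM, 0.856. Genes that depart from it may have bounds that hold more than counting error, so their fragment ratios are no independent check. For RpL10, RpL15, RpS7, Hsp83, osk, orb, zip, spen, mask, kis, lncRNA:Hsromega and hpRNA:CR33940 the FPKM and fragment ratios differed 1.35-fold to 1.86-fold. By this measure the IgG-RIP library held about 2661722 fragments on listed genes and the Lsd1-RIP library about 2494964. Without ribosomal RNA loci, pseudogenes included, these were 1039524 and 1201797. Fragments per FPKM, averaged over both libraries on the log scale, gave an implied transcript length for genes with at least 20 fragments in each library. It may be too small for abundant genes with wide bounds. eEF1alpha1, with a locus of 4628 nt and a mean FPKM of 1678, had 1.86, and Arc1, with 2371 nt and 23.5, had 36.4. The shortest of 12 length groups had a median mean FPKM of 16.7, against 5.92 in the next. Lists matched on length are matched on this value, and so in part on abundance. Intervals on ratios are 2 standard errors either way from the deposited bounds. At most they cover counting error and uncertainty of assignment, not the variation between repeated precipitations.

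The measure for each gene was log2 of (Lsd1-RIP FPKM + 1) over (IgG-RIP FPKM + 1). The pseudocount of 1 understates the change of genes with low FPKM. Where a plain fold is given, it is the ratio of the deposited FPKM. Eligible genes had status OK in both libraries and a mean FPKM of 1 or more. A gene was counted as higher or lower when the measure reached 1 or -1, which is called 2-fold. Noncoding RNA classes were assigned from symbols and biotypes, and gene lists for ovarian, chromatin, housekeeping and other-tissue functions were written before the data were examined. The hairpin RNA class was added after the values were seen, as were the use of biotypes for symbols outside the classes and the order in which overlapping class rules applied. The place of a list or class was described by the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins, for lists with 5 or more eligible members. This describes these libraries and is not a test between conditions. A median above the 97.5 or below the 2.5 percentile is called outside the range of random lists. For 19 lists and 8 classes it was given.

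Genes named in the text followed a rule fixed before the data were examined. It took eligible genes listed above 0 in both libraries: the 10 highest and 10 lowest ratios, the next 8 noncoding RNAs, up to 2 highest and 2 lowest per class and list, the members of the Lsd1 complex list, the 3 most abundant genes per library, and the 2 of highest FPKM among genes listed at 0 in either library. Genes outside that rule are said to have been singled out afterwards. The calculation was tested on simulated data for 5964 genes of this comparison. Of 50 genes each, 96% raised 3-fold and 100% raised 6-fold were called higher, and 50% lowered 3-fold and 68% lowered 6-fold were called lower, so the measure was less able to find lower genes. Of 5764 unchanged genes 0.156% were called. Both simulated libraries were drawn from the IgG-RIP values with counting error only, no offset between them and no genes listed at 0. The 0.156% is therefore no rate of false calls in the real libraries.

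Alternatives fixed in advance changed the pseudocount, the minimum FPKM, the scaling between libraries, the threshold and the use of genes under 200 nt. Alternatives chosen after seeing the data left out genes listed at 0 in 1 library, left out genes whose locus overlaps another, or removed the median ratio of genes of like implied length. Another took log2 of the ratio of approximate fragments, scaled by the depth ratio and with no pseudocount, for genes with at least 20 in each library, both as such and with its all-gene median removed. For named genes that overlap a gene of 200 nt or more listed at 0 in one library, the fragments of both were also summed, and their ratio was taken with no pseudocount after scaling by the depth ratio of 0.855. Random lists matched on implied length were also added then. Alternatives used 2000 random lists. A median counted as moved when it left its bootstrap range over members, and a gene when it left its ratio interval, both rules set after the data were seen. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.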

Results

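RNA bound in ovary lysate was measured in 2 libraries, 1 from a precipitation with an antibody against Lsd1 and 1 from the control precipitation of the same lysate. Lsd1, the product of Su(var)3-3, is a histone demethylase that acts in chromatin silencing. The IgG-RIP table listed 9435 genes above 0 and 8285 at 0, and the Lsd1-RIP table listed 9542 above 0 and 8178 at 0. The 4 ribosomal RNA loci listed above 0, all of them 28S rRNA pseudogenes, held 60.9% of the approximate fragments in the IgG-RIP library and 51.8% in the Lsd1-RIP library. Another 23 ribosomal RNA loci had too many fragments to be estimated and are in neither share. The 3 most abundant genes with an estimate were the same in both libraries, the 28S rRNA pseudogenes 28SrRNA-Psi:CR41609, 28SrRNA-Psi:CR45860 and 28SrRNA-Psi:CR45848. A median eligible gene rested on 86.4 fragments in the IgG-RIP library and 101 in the Lsd1-RIP library.

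The comparison of the Lsd1-RIP with the IgG-RIP library addresses which RNAs, noncoding RNAs above all, were recovered with Lsd1. The RNAs with the highest ratios were hairpin RNAs, long inverted-repeat transcripts of the kind processed into endogenous small interfering RNAs, together with Arc1, a Gag-like gene whose protein forms capsids, and its neighbouring pseudogene CR10102. The lowest ratios of FPKM included mRNAs of ribosomal proteins and that of zip, the heavy chain of nonmuscle myosin. Most genes lay between: 97.2% of the 6025 eligible genes were within 2-fold, and log2 FPKM correlated across genes with a Pearson r of 0.945, genes not being independent replicates.

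Of the eligible genes, 128 were at least 2-fold higher and 42 at least 2-fold lower in the Lsd1-RIP library, so 75.3% of these calls were higher. The median log2 ratio was 0.32 (middle 50% of genes, 0.13 to 0.52), a 1.25-fold offset, and groups are therefore described relative to it. With ratios centred on that median, 62 genes were higher and 63 lower, and 49.6% of calls were higher. Among genes listed above 0 in both libraries, 102 were higher and 7 lower. By approximate fragments scaled by depth, for the 5472 eligible genes with 20 or more in each library and with no pseudocount, 401 were higher and 0 lower. The all-gene median of that measure was 0.43, against which fragment ratios are to be read, and with it removed 43 genes were higher and 34 lower. The other 26 higher and 35 lower genes were listed at 0 in one library, and most of those of 200 nt or more overlapped another locus.

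**Figure D1:**
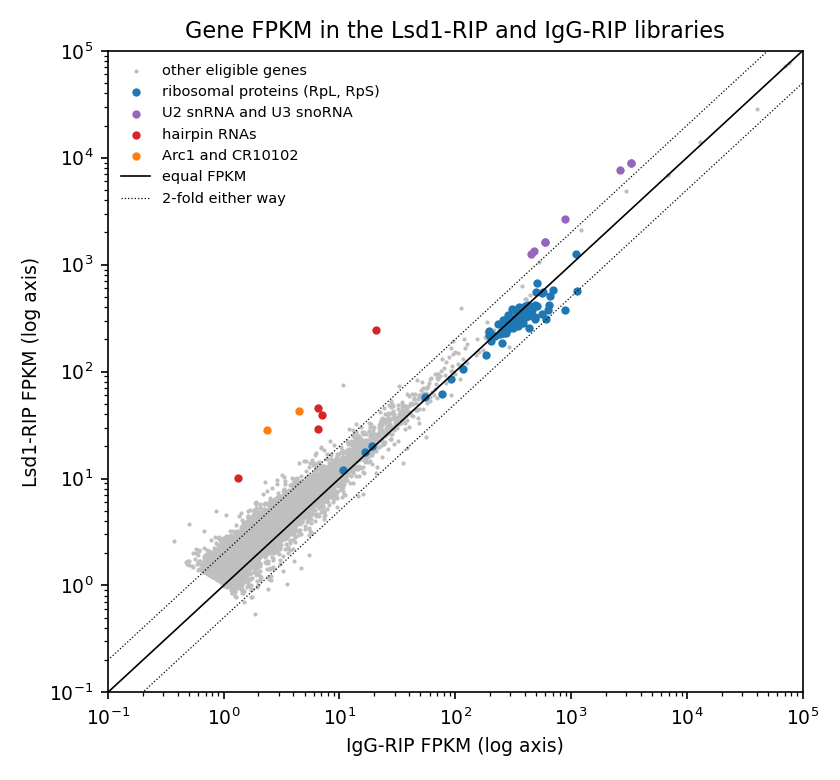
FPKM of each eligible gene listed above 0 in both libraries, IgG-RIP on the x axis and Lsd1-RIP on the y axis, both log axes; 1 point is 1 gene, the solid line marks equal FPKM and the dotted lines 2-fold either way. The hairpin RNAs, Arc1, CR10102 and the U2 and U3 RNAs lie above the upper dotted line, and the ribosomal protein mRNAs lie around and below the line of equal FPKM.

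All 5 eligible hairpin RNAs were higher in the Lsd1-RIP library, by 4.45-fold to 11.9-fold. hpRNA:CR33940 (3L:19486745-19488439) had an FPKM of 20.6 in the IgG-RIP library and 246 in the Lsd1-RIP library, a log2 ratio of 3.51 (interval 3.31 to 3.71). By this measure it was the highest of any eligible gene listed above 0 in both. On the same arm, hpRNA:CR32207 (3L:19477329-19478720) went from 6.54 to 45.2 and hpRNA:CR32205 (3L:19420390-19424183) from 7.08 to 39.5. hpRNA:CR46342 (X:4921677-4928133) went from 1.32 to 10.2, and hpRNA:CR18854 (2L:9787294-9790745) from 6.55 to 29.2. None of the 5 had deposited intervals that overlapped between the libraries. The other 3 of the 8 annotated hairpin RNAs were listed at 0 in both. The group was defined after its values were seen, and each of the 5 overlaps another annotated locus, which these libraries cannot separate by strand.

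Arc1 (2R:14357927-14360297) had an FPKM of 4.51 in the IgG-RIP library and 42.4 in the Lsd1-RIP library, a log2 ratio of 2.98 (interval 2.79 to 3.17). CR10102 (2R:14360433-14361780), the pseudogene beside it, went from 2.37 to 28.2, a log2 ratio of 3.12. By approximate fragments CR10102 was at 3.57 and Arc1 at 3.28, above hpRNA:CR33940 at 3.09. Arc2, a related gene singled out afterwards, had an FPKM of 0.24 and 0.28. The pseudogene CR42842, which lies inside the locus of hpRNA:CR32207, went from 10.7 to 74.6. The top 10 closed with scaRNA:PsiU2-55 (178 nt) at 1.79 and sisRNA:3, a stable intronic RNA, at 1.69. Both rest on 5 or fewer approximate fragments per library, and their ratio intervals spanned 0.

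**Figure D2:**
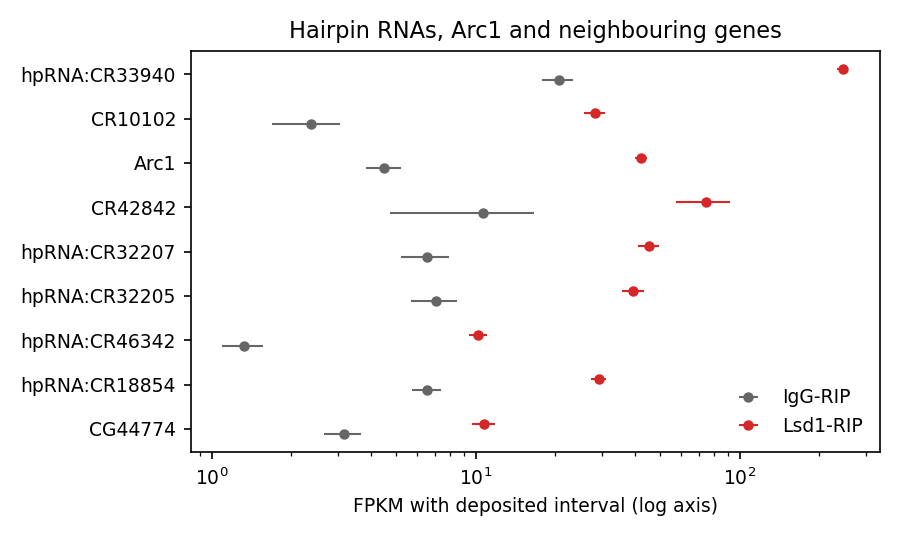
FPKM (log x axis) of the 5 eligible hairpin RNAs, Arc1, CR10102, CR42842 and CG44774, the last singled out afterwards, in the IgG-RIP (grey) and Lsd1-RIP (red) libraries. Points are the deposited values of 1 library each, and bars are their deposited intervals, which do not cover variation between precipitations. In each of these genes the red interval lies to the right of the grey one, with the widest separation at hpRNA:CR33940, 20.6 against 246.

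Several small nuclear and nucleolar RNAs of the spliceosome and of ribosome assembly were also higher in the Lsd1-RIP library. The U2 snRNA copy snRNA:U2:34ABa (192 nt) had an FPKM of 2646 in the IgG-RIP and 7660 in the Lsd1-RIP library, a log2 ratio of 1.53 (interval 1.34 to 1.73), and the U2 copies 14B, 38ABa and 34ABc, each of 192 nt, were 2.82-fold, 2.82-fold and 2.72-fold higher. The U3 snoRNA, which acts in processing of the pre-rRNA, had ratios of 1.57 for snoRNA:U3:9B (168 nt) and 1.44 for each of snoRNA:U3:54Aa and snoRNA:U3:54Ab (173 nt). Copies of U2 and of U3 are near-identical, so how fragments were divided among them is uncertain. The minor-spliceosome RNAs differed from U2: snRNA:U11 had a ratio of 0.29 and snRNA:U12 of 0.00, from 114 in each library. The 4 eligible U1 copies were listed at 0 in the Lsd1-RIP library with under 1 approximate fragment in the other, too few for any comparison. With them the snRNA class had a median of 0.29 over 11 members (percentile 67.6). Without them it was 1.44 over 7 members (percentile 100), which is the value of snRNA:U2:34ABc. The near-identical U2 copies count as separate members, so this median and percentile rest largely on U2. Of 30 annotated snRNA genes, 19 were listed at 0 in both libraries.

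The snoRNA class, with 13 eligible of 325 annotated, had a median log2 ratio of 0.89, above 10000 random lists of like expression, and 0.75 without the 4 members listed at 0 in one library. Of its 6 members at least 2-fold higher, 3 were the near-identical U3 copies, which count as separate members. The others were listed at 0 in the IgG-RIP library and rest on 1 approximate fragment each. Among abundant structural RNAs, snRNA:7SK, which holds the elongation factor P-TEFb inactive, went from 526 to 1054, 2.01-fold higher (log2 interval 0.92 to 1.08), and RNaseMRP:RNA from 374 to 633. The 2 7SL RNA genes of the signal recognition particle, which are near-identical, had ratios of 0.01 each. As a class, the 5 structural RNAs had a median of 0.22, within the range of random lists (percentile 58.8). The snoRNA host genes had a median of 0.03 over 6 members, below the range of random lists (percentile 2.29), with Uhg4 at 0.46 and Uhg8 at -0.33; this median was below 0 under each rescaling of the libraries.

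Long noncoding RNAs had a median log2 ratio of 0.52 over 39 eligible members of 1962 annotated, and 24 of the 39 were above the all-gene median. lncRNA:CR45666 was at 1.67 with under 2 approximate fragments in each library, too few for any comparison. At the other end, lncRNA:CR40469 had a ratio of -0.77 and lncRNA:CR43604 of -1.30, the latter with an interval spanning 0 and at most 6 approximate fragments. The median turned to -0.26 when genes with a mean FPKM under 5 were left out, and was 0.0832 with no minimum. The 9 eligible antisense RNAs had a median of 0.81, or 0.65 without members listed at 0 in one library. With no minimum FPKM, which takes in further members of lower FPKM, it was 0.0569. With the median of genes of like length removed it was 0.18, over fewer than 5 of the 9 members. These medians are over different members, so their differences do not measure an effect of length. asRNA:CR43430 was 2.13-fold higher, from 3.68 to 7.84. Without strand, fragments from an antisense RNA and its partner cannot be separated. Pseudogenes were not set apart (median 0.23, percentile 17.2). All 297 tRNA genes and 260 miRNA precursors were listed at 0 in both libraries, as were the 38 mitochondrial genes. For 2 of the miRNA precursors the status was HIDATA, so their 0 is a failed estimate. The options of Cufflinks are not given in the sources used here. Whether the other genes of these classes were left out of the estimate is therefore unknown, and their 0 need not mean absence.

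**Figure D3:**
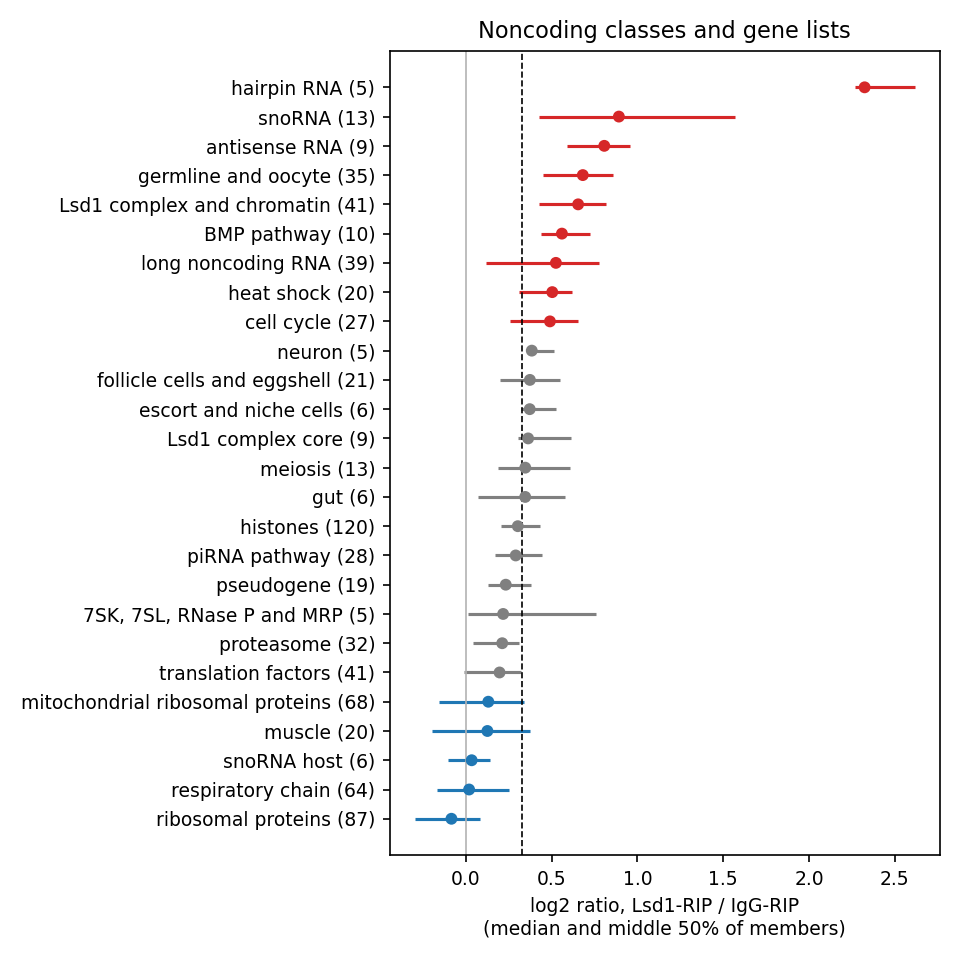
Median log2 ratio (points) and the middle 50% of members (bars) for noncoding classes and gene lists, with the number of eligible members in brackets; the dashed line is the all-gene median of 0.32, and the snRNA class is left out because its U1 members were listed at 0 in one library. Red medians lie above and blue ones below the middle 95% of expression-matched random lists, from hairpin RNA at 2.32 to ribosomal proteins at -0.08. The hairpin class was defined after its values were seen, so its colour is no independent result.

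Among protein-coding genes, mRNAs of germline and oocyte genes and of chromatin regulators had ratios above the all-gene median, and mRNAs of ribosomal proteins had ratios below it. In the germline list 33 of 35 eligible genes were above the median, and the list median was 0.68, above all 10000 random lists. With the all-gene median of each measure removed, it was 0.36 by FPKM and 0.15 by approximate fragments, above all random lists in both. nos, which encodes the translational repressor of the posterior pole, went from 6.96 to 19.2 (log2 ratio 1.34, interval 1.15 to 1.54), and bcd, the anterior determinant, from 1.61 to 4.95 (1.19). nos overlaps Nsun5, singled out afterwards, which had 85.0 approximate fragments in the IgG-RIP library and was listed at 0 in the other. Summed over both genes, the log2 ratio of fragments was 0.94. osk and orb, singled out afterwards, had ratios of 0.84 and 1.04, but by approximate fragments they were at 0.41 and 0.48, within 0.06 of the all-gene median of that measure. The lowest germline members were vls at -0.31 and spn-E at 0.19.

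Of 41 eligible genes in the list of Lsd1 partners and chromatin regulators, 33 were above the all-gene median, and the list median was 0.65, again above all random lists. trx, a histone methyltransferase gene of the Trithorax group, went from 1.68 to 5.03 (log2 ratio 1.17), and Sin3A, a corepressor scaffold, from 5.85 to 14.3 (1.16). E(z), the Polycomb methyltransferase, was at -0.03 and the HP1a gene at 0.01. Both trx and Sin3A have long transcripts, and with the median of genes of like length removed their ratios were 0.56 and 0.55. Sin3A overlaps ClC-b, singled out afterwards and listed at 0 in the Lsd1-RIP library, and the summed fragments of both gave 0.94. Among random lists matched on length, the germline and chromatin list medians stayed above all. With the median of genes of like length removed, the germline median was 0.30, above all random lists, and the chromatin median 0.12, at percentile 99.55.

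The BMP pathway list (10 genes, median 0.56, percentile 98.0), the heat shock list (20 genes, 0.50, percentile 99.04) and the cell cycle list (27 genes, 0.49, percentile 97.6) also lay above the range of random lists. Of 13 alternatives, 7 took the cell cycle list back into the range, 6 the BMP list and 2 the heat shock list. vkg, a collagen IV gene, had a log2 ratio of 1.29 and the BMP receptor gene sax 0.97. Hsp70Aa and Hsp70Ab, near-identical copies, were at 0.92 each, while Hsp83 was at -0.39 (0.14 by approximate fragments). dup, a replication licensing gene, was at 0.99 and Incenp at -0.15. For the BMP list the percentile was 93.0 among random lists matched on length.

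Ribosomal protein mRNAs formed the lowest list by FPKM. Only RpS23 of 87 eligible genes lay above the all-gene median, and the list median was -0.08, below all 10000 random lists. RpL10 (3L:23093190-23095471) was 2.35-fold lower in the Lsd1-RIP library, from 887 to 378 (log2 ratio -1.23, interval -1.32 to -1.14). RpL15 and RpS7 were at -0.98 and -0.97. By approximate fragments the 3 genes were at -0.34, -0.26 and -0.09 and the list median was 0.0773. For these genes the FPKM and fragment ratios differed 1.86-fold, 1.65-fold and 1.85-fold, so their bounds may hold more than counting error. Neither measure settles the size of their change. With the all-gene median of each measure removed, the 3 genes were at -1.55, -1.30 and -1.30 by FPKM and -0.77, -0.69 and -0.52 by fragments, and the list median was -0.35 by fragments and below all random lists. The respiratory chain (64 genes, median 0.02, from ND-13B at -0.63 to ND-B14.5A at 0.78) also lay below all random lists. So did mitochondrial ribosomal proteins (68 genes, 0.13, from mRpS21 at -0.96 to mRpS18C at 0.77). The medians of both lists turned negative under centring and under scaling to equal sums, and that of the respiratory chain also on the TPM scale. Among random lists matched on implied length, the ribosomal protein median stayed below all of them, the respiratory chain was at percentile 0.705, and the mitochondrial ribosomal proteins were at 8.58. For abundant genes such as RpL10 implied length may be too small, so this match is in part one on abundance.

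Other genes among the 10 lowest were CG15525 and CG1354 (-1.16 each) and the pseudogene CR31054 (-1.14). zip (2R:24990570-25011965) went from 15.9 to 7.24 (-1.03, interval -1.16 to -0.90, or -0.70 by approximate fragments and -1.13 with their median removed), and up, which encodes troponin T, from 38.6 to 19.3 (-0.96). CG15525 and CR31054 overlap other loci. MED9, a subunit gene of the Mediator complex, had a ratio of -1.22 taken alone, from 51.6 approximate fragments to 7.78. It lies inside the locus of CG42518, singled out afterwards, which held 0 fragments in the IgG-RIP library and 44.7 in the Lsd1-RIP library. The log2 ratio of their summed fragments was 0.25, below the all-gene median of 0.43 for fragment ratios.

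The mRNA of the Lsd1 gene and those of its partners CoRest and HDAC1 lay close to the all-gene median. Since the antibody acts on protein, these values check no label. Su(var)3-3 (3L:20226381-20230250) had an FPKM of 0.93 in the IgG-RIP and 1.39 in the Lsd1-RIP library, a log2 ratio of 0.31 (interval 0.04 to 0.59), which was -0.01 after centring. CoRest, the corepressor partner of Lsd1, was at 0.30 and HDAC1 at 0.36. ttk was at 0.83, ova at 0.79, Su(var)2-10 at 0.61, Sfmbt at 0.49 and egg at 0.28. The 9 genes, the HP1a gene included, had a median of 0.36 (percentile 61.3).

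Genes of the piRNA pathway, which silences transposons in the ovary, were not set apart as a list (28 genes, median 0.29, percentile 26.2), although squ was at 1.19 and del at 0.84, while moon was at -0.38 and arx at -0.36. Follicle cell and eggshell genes had a median of 0.37 over 21 genes (percentile 85.0), from ttk at 0.83 and Pxt at 0.72 to Vml at -0.25. The escort and niche cell list (6 genes, 0.37), the meiosis list (13 genes, 0.35), the proteasome (32 genes, 0.21) and translation factors (41 genes, 0.20) lay within the range of random lists, as did the 120 eligible histone genes (0.30), whose copies are near-identical. Among random lists matched on length, the histone median lay above all of them. The proteasome and translation factor medians were below 0 under centring and under scaling to equal sums. Within these lists LamC was at 0.62, spn-A at 0.84, Rpn5 at 0.53 and eEF1alpha1 at 0.80. At the low ends zfh1 was at 0.21, vilya at -0.16, Rpt5 at -0.29 and eIF3m at -0.25.

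Markers of tissues that a dissection can carry along were mixed. The muscle list lay below the range of random lists (20 genes, median 0.13, percentile 1.96), with up at the low end and Zasp52 at 0.84 and Msp300 at 0.81 at the high end, and its median was negative under centring and scaling to equal sums. Of the 13 alternatives, 4 took the list back into the range. Gut (6 genes, 0.35) and neuron (5 genes, 0.38) lists lay within the range. Jon65Aiv, a gut protease gene, was at 1.02 and Jon65Aiii at -0.36. In the neuron list unc-13, a synaptic gene, was at 1.12 and norpA at 0.23. Of the fat body list FASN1 alone was eligible, at 0.82. Of 4 eligible hemocyte genes, which include vkg, the others were Ppn at 0.86, crq at 0.40 and srp at 0.37. No cuticle gene was eligible.

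Across 5472 genes with an implied length, the ratio was higher for longer transcripts (Spearman's rho 0.403 across genes, which are not independent replicates). Among the genes named here, the long mRNAs of trx and Sin3A lay above the all-gene median and most short mRNAs of ribosomal proteins below it. zip, with a locus of 21396 nt, had a low ratio, and the hairpin RNAs stood above genes of like length.

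**Figure D4:**
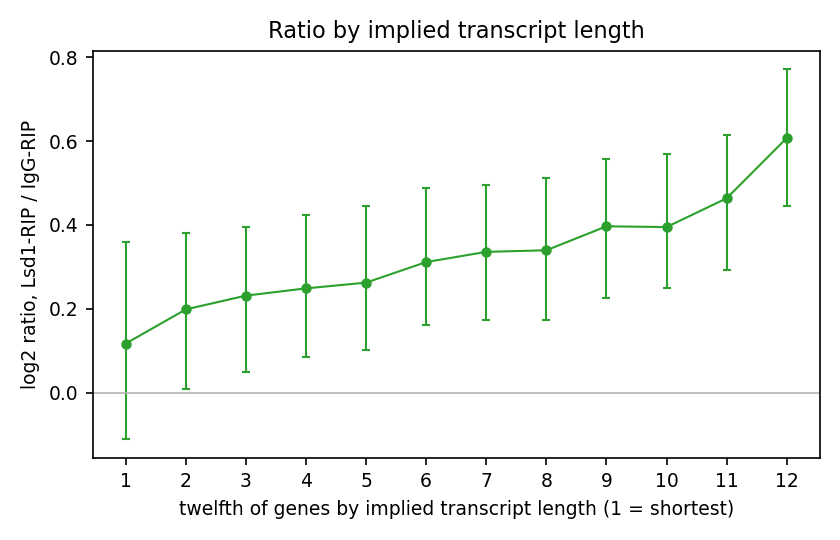
Median log2 ratio (points) and the middle 50% of genes (bars) in 12 groups of 456 genes ordered by implied transcript length, shortest first. The median lies at 0.12 in the shortest group and 0.61 in the longest.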

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

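Tests chosen only after the data were seen were those without genes listed at 0, without overlapping loci, with the length median removed, with approximate fragments in place of FPKM (also with their median removed) and with fragments of overlapping genes summed. Of 156 values for the main results under alternatives, 109 stayed within their range, and of 1976 others 1442 did. Of the named genes that were at least 2-fold, MED9 alone changed sign, to 0.25 when summed with its overlapping gene listed at 0. That value is still below the all-gene median of 0.43 for fragment ratios. No paired analysis was possible because each group had 1 library. The count of genes 2-fold higher, 128, became 476 and 32 with pseudocounts of 0.1 and 5, 70 at a mean FPKM of 5 or more, 62 after centring, 225 with FPKM rescaled to a common sum (TPM scale), 71 at equal sums, 56 without overlapping loci, 22 with the length median removed, 401 by approximate fragments, 43 with the median of these removed and 25 at 4-fold. The count lower, 42, became 15 (pseudocount 5), 66 (no minimum), 11 (mean of 5), 7 (no genes listed at 0), 6 (no overlapping loci), 9 (length), 0 (approximate fragments), 34 (the same with their median removed) and 23 (4-fold). Protein-coding lists outside the range of random lists were 9. With the pseudocount of 5 they were 5, without BMP, cell cycle, heat shock and muscle. With no minimum and by approximate fragments, with or without their median, they were 6, without BMP, cell cycle and muscle. At a mean of 5 or more they were 7, without BMP and cell cycle, and without genes under 200 nt they were 8, without cell cycle. Without overlapping loci they were 8, without cell cycle and heat shock and with the Lsd1 complex core, and with the length median removed 9, with histones in place of BMP. By approximate fragments the ribosomal protein median was 0.0773. With the all-gene median of that measure removed, values were 0.30 for antisense RNA, 0.0693 for long noncoding RNA, -0.0934 for pseudogenes, -0.28 for snoRNA hosts, -0.21 for structural RNAs, -0.29 for mitochondrial ribosomal proteins, -0.27 for muscle and -0.39 for the respiratory chain. Su(var)3-3 was at -0.0121 after centring and -0.0827 with the length median removed. Medians at a pseudocount of 5 were 1.88 for hairpin RNA, 0.22 for long noncoding RNA and 0.10 for pseudogenes. With no minimum they were 0.0569 for antisense RNA, 0.0832 for long noncoding RNA and 0.0895 for pseudogenes, and at a mean of 5 or more -0.26 and 1.29 for the last pair. Centring gave 0.20 for long noncoding RNA, -0.0921 for pseudogenes, -0.11 for structural RNAs, -0.29 for snoRNA hosts, -0.19 for mitochondrial ribosomal proteins, -0.20 for muscle and -0.31 for the respiratory chain. Equal sums gave 0.0660 for pseudogenes, -0.0214 for structural RNAs, -0.16 for snoRNA hosts, -0.0692 for mitochondrial ribosomal proteins, -0.0895 for muscle and -0.21 for the respiratory chain. The TPM scale gave -0.0645 for snoRNA hosts and -0.0827 for the respiratory chain. Without overlapping loci muscle was at -0.19 and the respiratory chain at -0.0427. With the length median removed, values were 0.18 for antisense RNA, 0.26 for long noncoding RNA, 0.000814 for pseudogenes, -0.0374 for snoRNA hosts, -0.0457 for mitochondrial ribosomal proteins, -0.16 for muscle and -0.17 for the respiratory chain. Centring, scaling and the length median subtract an offset by construction, the filters remove genes, and otherwise the cause was not tested. The length median and approximate fragments also keep only genes with at least 20 fragments in each library, so medians can shift through lost members. Antisense RNA, hairpin RNA and snoRNA hosts had no member left without overlapping loci, and meiosis none at a mean of 5 or more. Depth limits low genes most, and repeated precipitations would be needed to measure the spread between libraries.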

Other observations

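Of the tests below, those on hairpin copies, on hairpin length, on fragments held by overlapping genes, on fragment length and on too few fragments were chosen only after the result was seen. Some of the protein-coding genes with the next highest ratios are given here, singled out afterwards and with no enrichment tested. Bre1, a ubiquitin ligase gene for histone H2B, went from an FPKM of 2.29 to 9.35 (log2 ratio 1.65, interval 1.44 to 1.87). upSET, a SET domain gene, was at 1.47, spen, a corepressor gene, at 1.45, and kis, a chromatin remodeller of the Trithorax group, at 1.36. mask was at 1.40 and Cirl, a latrophilin receptor gene, at 1.37. wisp, the cytoplasmic poly(A) polymerase of late oogenesis, went from 5.16 to 14.7 (1.35), and Vap33 from 8.37 to 22.3 (1.31). CG44774, which overlaps hpRNA:CR46342, was 3.40-fold higher. By approximate fragments spen was at 1.13, mask at 1.11 and kis at 0.95, against an all-gene median of 0.43. With the median of genes of like length removed, Bre1 stood at 1.26, spen at 0.84 and kis at 0.75.

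Also singled out afterwards, lncRNA:Hsromega, a nuclear RNA of the heat shock response, went from 13.7 to 24.0 (log2 ratio 0.77), but was at 0.01 by approximate fragments, below the all-gene median of 0.43, and snoRNA:Psi28S-291 from 2979 to 4852 (0.70). Genes listed at 0 in one library included snoRNA:SC35-a (153 nt), at 539 in the Lsd1-RIP library, and snoRNA:Psi18S-531 (152 nt), at 648 in the IgG-RIP library. Both values rest on 1 approximate fragment.

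For the high ratios of the hairpin RNAs, counting 1 locus several times on 3L does not account for the loci on other chromosomes, where the lowest log2 ratio was 1.999, though it stays open among the 3 loci on 3L. Length does not account for the 5 loci: with the median of genes of like implied length removed, their log2 ratios were 1.66 to 3.31. Their percentile of 100 among lists matched on implied length adds little, since the class was defined from its values. Fragments lost by the overlapping gene were 5.76% of those gained at hpRNA:CR18854 and 0% at hpRNA:CR32207 and hpRNA:CR46342, too little to account for them. At hpRNA:CR32205 and hpRNA:CR33940 the overlapping genes were listed at 0 in both libraries. By this count they held 0 fragments in the IgG-RIP library to lose, and neither had the status HIDATA. Why they were at 0 was not tested. RNA of an overlapping gene that itself was recovered more cannot be told apart, since 0 of the 5 loci are free of overlaps and strand was not marked. Shared fragments may also have been assigned to the hairpin RNA. Of the overlapping genes, singled out afterwards, CR42842 and CG44774 were higher too, CR33255 and CG32212 were listed at 0 in both libraries, and IP3K1 had 1.70 and 0. No biological explanation was tested, and 1 library per group cannot exclude variation between precipitations.

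The ratio was higher for longer transcripts. Across 5472 genes Spearman's rho was 0.394 with locus span, which does not rest on the bounds. With implied length it was 0.403 (0.456 by approximate fragments), and the median log2 ratio was 0.12 in the shortest of 12 groups and 0.61 in the longest. A different fragment length in the libraries cannot be told apart: the effective length ratio moved by -0.033 on the log2 scale between those groups, but 518 genes with whole fragments and loci of 221 to 104437 nt shared 1 ratio of fragments per FPKM, so 1 length model may have served both libraries. Housekeeping lists were not the whole of it (rho 0.373 without them), nor was abundance (lowest rho 0.364 within bands of mean FPKM). RNA integrity and the unspliced share in each precipitate were not tested and may differ, as may the biology of Lsd1, so germline and chromatin genes, many of them long, are best read beside their length-matched percentiles.

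Genes listed at 0 in one library fell into separate kinds. Of 51 such genes of 200 nt or more, 22 were at 0 in the IgG-RIP and 29 in the Lsd1-RIP library, among them grk and Su(var)3-9, singled out afterwards, at 0 in the IgG-RIP library. Their median was 40.6 fragments in the library that listed them, so too few fragments does not account for the set, but it stays open for the 4 genes with under 5 fragments, which include the 2 that overlap no other locus. Of them 96.1% overlapped another locus (exact 95% interval 86.5% to 99.5%) against 50.1% of eligible genes of that length, so a candidate explanation is assignment of shared fragments to the overlapping gene, and no biological explanation was tested. The 10 genes under 200 nt had a median of 1.0 fragment, consistent with too few fragments.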
